A study of Mus musculus with 9 samples.

How the data were processed

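RNA from 9 samples of the mouse breast carcinoma line D2A1-d was sequenced by the authors: 3 with a non-targeting control hairpin (NTC) and 3 with each of 2 short hairpin RNAs against Med1. Per the labels, total RNA was extracted on an automated instrument with a DNase step, and libraries were run on a BGISEQ-500 instrument. The authors deposited raw counts per gene, one file per sample, and per the submitters' processing notes STAR, HTSeq and the mouse build GRCm38 (mm10) were used. Versions, the annotation release and the strand setting are not given in the sources used here. Each file lists 55335 genes, with 0 lines that name no gene. Gene symbols and positions come from GENCODE annotation on GRCm38: 54587 identifiers matched with their version and 55154 without it. Reads shared by near-identical genes, and by genes that overlap on opposite strands, cannot be separated in such counts.

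Library totals were 8123918 to 8879982 counts. A count of 3 corresponds to 0.338 to 0.369 CPM in these libraries, and values near it have little precision. Counting intervals cover counting error only, since reads carry no molecular identifiers. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom from 1.55 to 2.53), which library preparation alone can also give. They were counted as separate samples because the labels call them biological replicates. The common biological coefficient of variation was 3.68%.

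Genes were kept by edgeR's filterByExpr with the group as factor, which left 13611. Counts were scaled by TMM, with factors from 0.982 to 1.02, and CPM values use the scaled library sizes, except the sums and bounds of leukocyte markers, which use the library totals. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) with 1 coefficient per group over all 9 samples and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. The contrasts were each hairpin against NTC, the mean of both hairpins against NTC, and shMed1 #4 against shMed1 #2. Fold changes are on the log2 scale with the standard error of the fit, and where 2 values follow a gene's name the first belongs to shMed1 #2 and the second to shMed1 #4. Overlap between the hairpins was set beside 20 simulations of unchanged groups that share the controls.

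Gene lists, 34 in number, were fixed before the data were examined, and the 30 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Counts of called members are given over all genes tested and adjusted over the list alone. Genes were named by a rule also fixed before the data were examined. It takes Med1 and Med4; the 12 highest and 12 lowest genes called with both hairpins in the same direction; the 6 highest and 6 lowest between the hairpins; up to 3 of each pattern of opposite calls; and up to 4 members of each list, those called with both hairpins first. Except for list members, it requires a mean of at least 1 log2 CPM and an assigned symbol that is not a predicted gene, clone or pseudogene. Plin4, Csf1r, Cd68, Lyz2 and Tsix, and the genes named from lists made later, fall outside that rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

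The scripts were tested on simulated counts for 13611 genes with 200 changed genes, 50 at each of 4 fold sizes. Of the 50 changed 2-fold the test recovered 92% for shMed1 #2 against NTC, 96% for shMed1 #4 against NTC, 100% for the mean of both hairpins and 98% between the hairpins. Of the 50 changed 1.2-fold it recovered 40%, 54%, 46% and 34%. False calls made up 3.95%, 6.74%, 3.51% and 4.38% of the calls, in the same order, against the 5% aimed at. Far more genes were called in the data than were changed here, so these shares hold for the simulated setting only. Alternatives fixed beforehand were RLE and upper quartile scaling, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, a fit without the robust option, only the groups compared, the replicate number as a block, a 2-fold minimum, each library left out in turn, an estimated correlation in camera, and limma's fry. Offsets for GC content and length, and a minimum of 4 log2 CPM, were added after seeing the data. Explanations for patterns were also tested after the patterns had been seen. Figures were drawn with matplotlib 3.10.9.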

Results

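RNA was measured in D2A1-d cells, a mouse breast carcinoma line, carrying either a non-targeting control hairpin (NTC) or 1 of 2 short hairpin RNAs against Med1, named shMed1 #2 and shMed1 #4. Each of the 3 groups held 3 samples, which the labels call biological replicates. Med1 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and is the subunit that binds nuclear receptors. The files held raw counts per gene. The library totals of replicates 1, 2 and 3 were 8123918, 8191344 and 8504098 counts in NTC. They were 8879982, 8773974 and 8824261 counts with shMed1 #2, and 8649028, 8347798 and 8592169 counts with shMed1 #4. In all, 13611 genes had enough counts to be tested. Nothing in the labels says whether the 3 samples of a group came from separate transductions or cultures, so the p-values measure only the spread between these samples, which may be technical.

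Med1 mRNA fell with both hairpins. Med1 (ENSMUSG00000018160.15, a protein-coding gene on the minus strand of chromosome 11, 98152154 to 98193293, GRCm38) stood at 85.6, 87.5 and 79.8 CPM (counts scaled to a common library size) in the NTC samples. It stood at 22.1, 25.2 and 24.7 CPM with shMed1 #2 and at 25.02, 26.6 and 25.5 CPM with shMed1 #4. The log2 fold change of Med1 was -1.81 (SE 0.0746, adjusted p = 5.67e-36) with shMed1 #2 and -1.71 (SE 0.0739, adjusted p = 6.39e-34) with shMed1 #4. Between the hairpins Med1 differed by 0.10 on the log2 scale, with a 95% interval from -0.08 to 0.28 (adjusted p = 0.461). Med4, the subunit named in the series title (ENSMUSG00000022109.6, chromosome 14, 73510025 to 73518849), averaged 28.3 CPM in NTC, 28.8 CPM with shMed1 #2 and 29.1 CPM with shMed1 #4, and neither difference passed the test (adjusted p = 0.855 and 0.793).

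**Figure D1:**
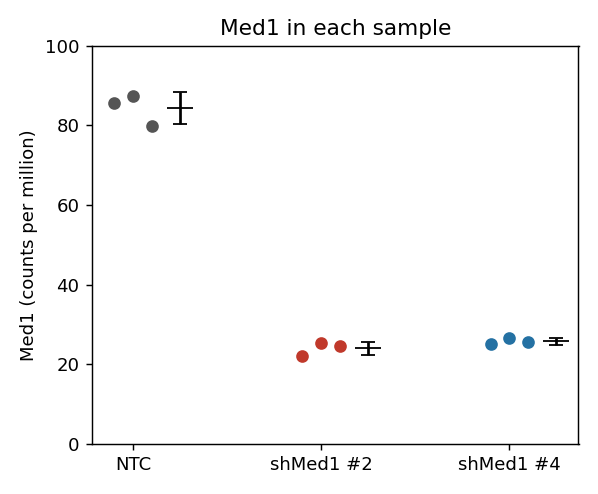
Med1 expression in CPM (vertical axis) in each sample of the 3 groups (points), with the group mean and SD beside them (black bars, n = 3). The NTC samples sit between 79.8 and 87.5 CPM, and all samples with a Med1 hairpin sit between 22.1 and 26.6 CPM.

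**Figure D2:**
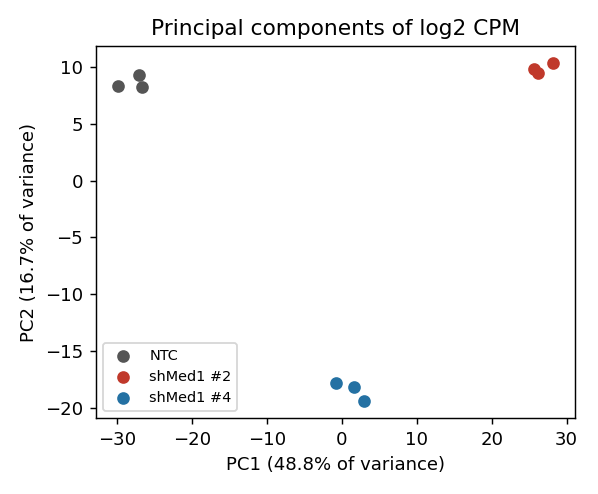
Principal components of log2 CPM, one point per sample, coloured by group, with the share of variance on each axis. The first component (48.8% of the variance) sets NTC and shMed1 #2 apart with shMed1 #4 between them, and the second (16.7%) sets shMed1 #4 apart.

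The first comparison asked which transcripts differed from NTC in cells with shMed1 #2. The epithelial adhesion gene Perp fell by 4.22 on the log2 scale (SE 0.199, adjusted p = 3.99e-32), from 21.8 to 1.16 CPM. The secreted glycoprotein osteopontin, Spp1, fell by 2.66 (SE 0.0605), from 899 to 142 CPM, and the fatty acid desaturase Scd2 fell by 1.86 (SE 0.0414), from 949 to 262 CPM. The regulator of G protein signalling Rgs16 rose by 2.06 (SE 0.0768), from 22.0 to 91.3 CPM, and the matricellular gene Ccn1 rose by 1.27 (SE 0.0595), from 381 to 917 CPM. At an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5947 genes were called, 2964 higher and 2983 lower. With a change of at least 2-fold required as well, 102 were higher and 511 were lower.

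The second comparison put the same question for shMed1 #4. Perp fell by 3.56 (SE 0.182, adjusted p = 2.99e-29), to 1.84 CPM. Spp1 fell by 1.11 (SE 0.0551), to 415 CPM, and Scd2 fell by 0.92 (SE 0.0396), to 502 CPM. Itga6, the integrin alpha 6 chain, rose by 1.35 (SE 0.111, adjusted p = 9.5e-18), from 11.6 to 29.7 CPM. The test called 3836 genes, 1911 higher and 1925 lower, of which 52 and 232 changed at least 2-fold.

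Genes called with both hairpins in the same direction numbered 2799, of which 1419 were higher and 1380 lower. By the rule set before the data were examined, the 12 highest included Parm1, Acta1, Itga6, Rgs16, Havcr2, Rnf165, Hes1, Lims2, Mrgpre, Adgrg1 and Kpna1. Parm1 rose by 1.99 and 2.04 on the log2 scale with shMed1 #2 and shMed1 #4, and the skeletal actin gene Acta1 by 1.68 and 1.81. The 12 lowest were Perp, Saa3, Cxcl12, Oasl2, Xist, Gbp3, Pcdh19, Ifit1, Enpp2, Rtp4, Ccn4 and Lgals7. The acute-phase gene Saa3 fell (-3.93 and -3.20), and Enpp2, which encodes autotaxin, fell (-2.79 and -2.50). Xist, the noncoding RNA that silences an X chromosome, averaged 154 CPM in NTC, 16.2 CPM with shMed1 #2 and 16.8 CPM with shMed1 #4 (log2 fold changes -3.25 and -3.20, each with an SE of 0.161). Its reads cannot be told from those of its antisense partner Tsix, since the strand setting of the counting is not given in the sources used here. Counts of Gbp3, Oasl2, Ifit1 and other members of multigene families are uncertain where reads could be split between near copies.

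Such an overlap would hold 416 higher and 422 lower genes if the lists were independent. Both comparisons use the same NTC libraries. In 20 simulations of unchanged groups set against shared controls, no gene was called with both. The simulated groups gave on average 0.05 and 0.15 calls against NTC, so hardly any overlap was possible there. NTC was drawn from the same means as the hairpin groups, so a shift of NTC itself, shared by both comparisons, was not simulated. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.706, against 0.507 in the simulations, and a covariance of 0.129, against 0.0144. The difference in covariance was 0.115. The 3 NTC libraries are too few to divide between the comparisons, so the part of the overlap that comes from shared controls was not measured apart from the simulations.

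**Figure D3:**
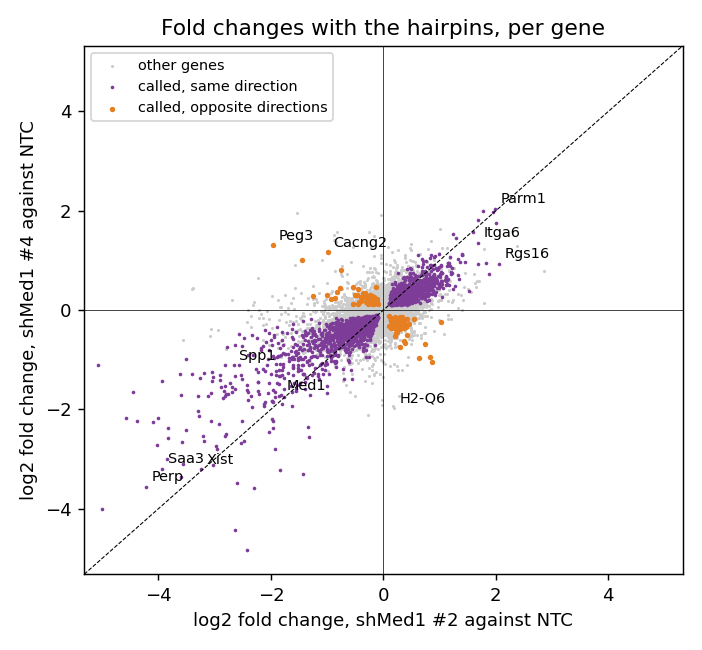
Log2 fold change against NTC of each of the 13611 genes tested, with shMed1 #2 (horizontal axis) and shMed1 #4 (vertical axis); the dashed line marks equal changes. The 2799 genes called in the same direction are purple, the 118 called in opposite directions orange, and all others grey.

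Genes of interferon response were lower with both hairpins. Of 23 tested interferon-stimulated genes, 20 were lower with shMed1 #2 (median log2 fold change -1.96), 20 were lower with shMed1 #4 (median -1.63), 19 were lower with both and 0 were higher. Adjusted over the list alone, the counts were 21 and 20 lower. Ifit1 fell (-2.81 and -2.53), Rtp4 fell (-2.93 and -2.29), and Oasl2, with 3 to 9 counts per library with shMed1 #2, fell (-4.03 and -2.71). In limma's camera test on the mean of both hairpins the list was lower with an adjusted p = 1.16e-11, and adjusted p = 0.0704 with an estimated correlation. NF-kB and cytokine genes were lower as well: 14 of 18 were lower and 0 higher on the mean of both hairpins, and 14 adjusted over the list alone (camera adjusted p = 1.71e-06, and adjusted p = 0.0225 with an estimated correlation). Of these 18 genes, 12 were lower with shMed1 #2, 9 with shMed1 #4 and 8 with both. The adhesion receptor gene Vcam1 fell (-2.56 and -1.11), and the chemokine gene Ccl5 fell (-1.86 and -1.74). Among leukocyte markers, Cd14 averaged 62.9 CPM in NTC, 42.9 CPM with shMed1 #2 and 55.2 CPM with shMed1 #4 (adjusted p = 2.58e-10 and 0.0268). The call of Cd14 with shMed1 #4 was lost in DESeq2 (adjusted p = 0.0981) and without NTC replicate 1 (0.0507), NTC replicate 3 (0.251), shMed1 #4 replicate 1 (0.0599) or shMed1 #4 replicate 2 (0.145).

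Lipid synthesis genes were lower with both hairpins. Of 23 genes of cholesterol biosynthesis, 22 were lower and 1 higher with shMed1 #2 (median -0.59), and 18 lower and 1 higher with shMed1 #4 (median -0.32). On the mean of both hairpins 22 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 6.58e-12, and adjusted p = 0.0225 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell (-1.07 and -0.66), Mvd fell (-1.41 and -0.79), and Insig1, a sterol-sensing regulator, fell (-1.09 and -0.47). Of 12 genes of fatty acid synthesis, 10 were lower with each hairpin, 1 was higher with shMed1 #2 and 0 with shMed1 #4, and 11 were lower and 1 higher on the mean of both, also adjusted over the list alone (camera adjusted p = 1.71e-06, and adjusted p = 0.0337 with an estimated correlation). Scd1 fell (-0.99 and -0.84), and the sterol regulatory factor Srebf1 fell (-0.82 and -0.46). Of 12 other nuclear receptor targets, 8 were lower with each hairpin and 0 higher, and 9 were lower adjusted over the list alone on the mean of both (camera adjusted p = 0.000109, and adjusted p = 0.0337 with an estimated correlation). The sterol exporter gene Abcg1 fell (-2.41 and -1.82), and the glucocorticoid-induced gene Tsc22d3 fell (-0.68 and -0.59). Of 15 PPAR targets and genes of fatty acid oxidation, 3 were higher and 4 lower on the mean of both hairpins, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.921).

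Endoplasmic reticulum chaperones and ATF4 targets were lower with both hairpins. Of 19 endoplasmic reticulum chaperones, 18 were lower with shMed1 #2 (median -0.69) and 17 with shMed1 #4 (median -0.46), with 18 adjusted over the list alone for each (mean of both hairpins, camera adjusted p = 2.04e-14, and adjusted p = 0.0228 with an estimated correlation). Creld2 fell (-1.21 and -0.70), Pdia4 fell (-1.16 and -0.58), and Hyou1 fell (-0.84 and -0.76). Of 20 ATF4 targets, 16 were lower and 0 higher on the mean of both hairpins, and 16 adjusted over the list alone (camera adjusted p = 5.08e-06, and adjusted p = 0.0704 with an estimated correlation). Of these 20 genes, 13 were lower with shMed1 #2, 15 with shMed1 #4 and 11 with both. With an estimated correlation the ATF4 list passed camera with shMed1 #4 (adjusted p = 0.0373) but not with shMed1 #2 (0.161). The pseudokinase gene Trib3 fell (-0.69 and -0.77), and the cystine transporter gene Slc7a11 fell (-0.26 and -0.95).

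As lists, genes of the actin cytoskeleton, mitosis and DNA replication were higher with each hairpin in camera. Called higher with both hairpins were 18 of 27 actin cytoskeleton and SRF target genes, 18 of 34 mitosis genes and 16 of 34 replication genes. Called lower with both were 1, 0 and 1. With an estimated correlation the lists passed with shMed1 #4 (adjusted p = 0.049, 0.0391 and 0.0373). They did not pass so with shMed1 #2 (adjusted p = 0.177, 0.177 and 0.163). Camera set each list against all genes, not against genes of like abundance. When only genes with a mean of at least 4 log2 CPM were tested, more were higher than lower against NTC. Lists of abundant genes, here and in the next paragraph, may in part be higher through this trend, which was not tested. Lists of scarcer genes, in any paragraph, may likewise in part be lower through it. On the mean of both hairpins 22 of 27 genes of the actin cytoskeleton and SRF targets were higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 4.1e-08, and adjusted p = 0.0819 with an estimated correlation). Srf rose by 0.72 and 0.54, Tagln by 1.16 and 0.50, and Myl6 by 0.61 and 0.47, while Tpm2 fell (-2.82 and -1.53). Of 34 genes of mitosis, 25 were higher and 0 lower, the same counts adjusted over the list alone (camera adjusted p = 1.22e-07, and adjusted p = 0.0787 with an estimated correlation). Anln rose by 0.48 and 0.42, and Cdk1, the kinase that drives entry into mitosis, by 0.36 and 0.41. Of 34 genes of DNA replication, 20 were higher and 2 lower, or 21 and 3 adjusted over the list alone (camera adjusted p = 3.24e-05, and adjusted p = 0.0704 with an estimated correlation). Pcna rose by 0.41 and 0.48, and Gins1, which encodes a part of the replicative helicase, by 0.34 and 0.37. Of 13 replication-dependent histones, 3 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.122 with an estimated correlation). The histones did not pass with shMed1 #2 alone (adjusted p = 0.178). The histone call on the mean was lost after a correction for GC content and length (adjusted p = 0.0528), and reads of near-identical histone genes cannot be separated.

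Further lists that passed on the mean of both hairpins held adhesion, growth, Mediator and oxidative phosphorylation genes. On that contrast 5434 genes, 39.9% of all tested, were called, 2680 higher and 2754 lower. The shares called of the TGF-beta and BMP, Mediator and oxidative phosphorylation lists were near that of all genes. Their direction, not the number called, sets these lists apart. Of 29 integrin and focal adhesion genes, 14 were higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.211 with an estimated correlation). Lims2, a focal adhesion adaptor gene, rose by 1.68 and 0.92, while Itgb8 fell (-3.19 and -1.26). Of 19 TGF-beta and BMP targets, 7 were higher and 1 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.009, and adjusted p = 0.0704 with an estimated correlation). Id1 rose by 1.04 and 0.75, and Pmepa1 by 0.48 and 0.69. Of 26 MYC and ribosome biogenesis genes, 14 were higher and 3 lower, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.00485, and adjusted p = 0.0936 with an estimated correlation). Ncl, which encodes nucleolin, rose by 0.37 and 0.20. Of 32 Mediator subunits other than Med1, 11 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.174 with an estimated correlation). With shMed1 #2 alone the Mediator list did not pass (12 higher and 6 lower, adjusted p = 0.0848). The Mediator call on the mean was lost with library size alone as scaling (adjusted p = 0.0567) and after a correction for GC content and length (0.0776). Med27 rose by 0.43 and 0.36, and Med30 by 0.35 and 0.35, but without shMed1 #4 replicate 3 neither was called with shMed1 #4 (adjusted p = 0.0619 and 0.0923). Of 75 nuclear genes of oxidative phosphorylation, 27 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.00422, and adjusted p = 0.274 with an estimated correlation). That list did not pass with shMed1 #2 (18 higher and 6 lower, camera adjusted p = 0.125). It passed with shMed1 #4 (25 higher and 1 lower, camera adjusted p = 0.000105, and adjusted p = 0.179 with an estimated correlation). Between the hairpins the oxidative phosphorylation list did not pass (camera adjusted p = 0.128). Uqcrb rose by 0.44 and 0.27.

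Another 11 lists did not pass on the mean of both hairpins. Of 16 dormancy-associated genes, 3 were higher and 7 lower, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.329). The cell cycle inhibitor gene Cdkn1a rose by 0.87 and 0.61, while Cdkn1b, another such inhibitor, fell (-0.41 and -0.43). Extracellular matrix genes (32 tested, 10 higher and 15 lower, also adjusted over the list alone) had a camera adjusted p = 0.422. Vcan, which encodes versican, fell (-1.40 and -1.60). Matrix remodelling enzymes (30 tested, 13 higher and 9 lower, also adjusted over the list alone) had a camera adjusted p = 0.109. Mmp3 fell (-2.91 and -1.41). Mesenchymal markers (13 tested, 3 higher and 3 lower, or 3 and 5 adjusted over the list alone) had a camera adjusted p = 0.617, with Vim higher by 0.57 and 0.38. Epithelial markers (5 tested, 1 higher and 2 lower, also adjusted over the list alone) had a camera adjusted p = 0.58, and the keratin gene Krt8 fell (-1.74 and -0.89). YAP/TEAD targets (20 tested, 9 higher and 5 lower, or 10 and 6 adjusted over the list alone) had a camera adjusted p = 0.139. Targets of p53 (20 tested, 9 higher and 9 lower, also adjusted over the list alone) had a camera adjusted p = 0.921, and Bbc3, which encodes a pro-apoptotic protein, fell (-1.56 and -0.82). Glycolysis and hypoxia genes (24 tested, 9 higher and 8 lower, or 12 and 8 adjusted over the list alone) had a camera adjusted p = 0.624. Wnt and Notch targets (9 tested, 3 higher and 3 lower, also adjusted over the list alone) had a camera adjusted p = 0.921, and Hey1 fell (-1.14 and -0.43). Immediate early and MAPK feedback genes (21 tested, 10 higher and 4 lower, or 11 and 4 adjusted over the list alone) had a camera adjusted p = 0.0682, or 0.0253 after a correction for GC content and length, and Dusp4 rose by 0.95 and 0.60. Ribosomal proteins (78 tested, 12 higher and 15 lower, also adjusted over the list alone) had a camera adjusted p = 0.997. The median and the mean log2 fold change differed in sign for matrix remodelling (0.14 and -0.11), p53 targets (0.14 and -0.36), epithelial markers (0.05 and -0.35), glycolysis and hypoxia (0.08 and -0.04), PPAR targets (0.04 and -0.04), Wnt and Notch targets (0.02 and -0.08) and ribosomal proteins (-0.013 and 0.0036). With shMed1 #4 alone, matrix remodelling enzymes (camera adjusted p = 0.0167, and adjusted p = 0.0518 with an estimated correlation) and immediate early genes (0.0456, and adjusted p = 0.211 with an estimated correlation) were higher. The call of immediate early genes was also lost with the replicate number as a block (adjusted p = 0.0517) and with library size alone as scaling (0.0509).

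**Figure D4:**
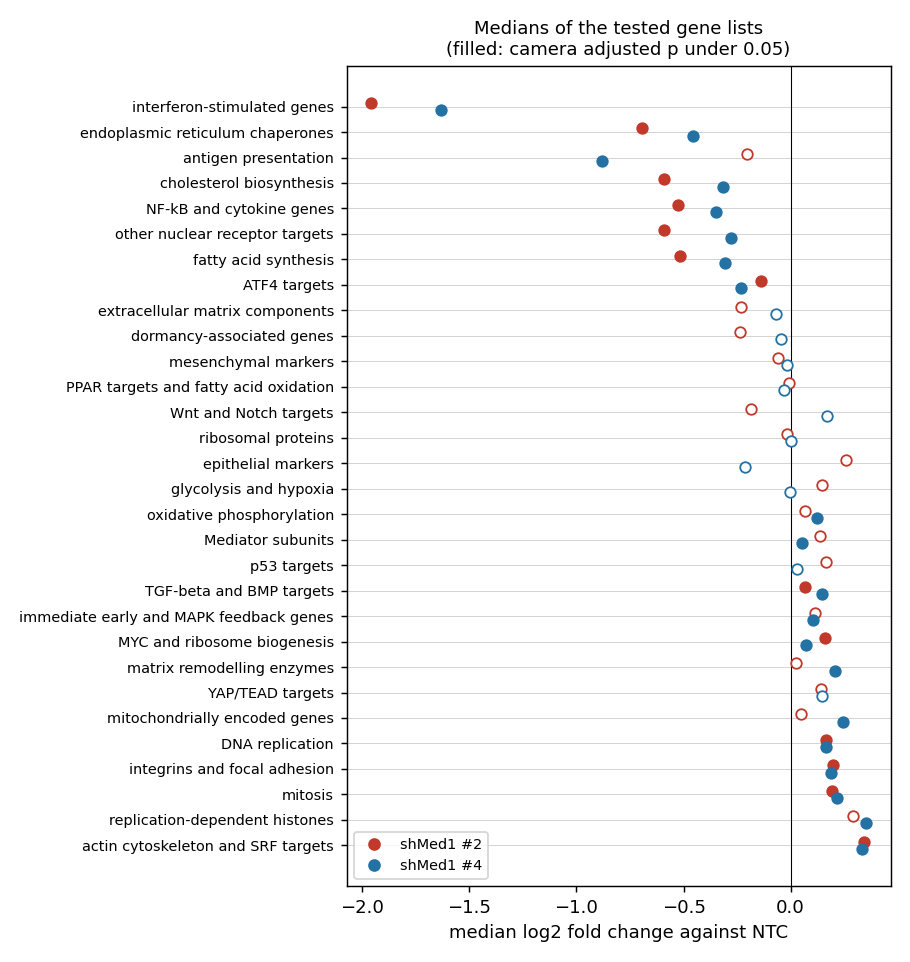
Median log2 fold change against NTC (horizontal axis) of each of the 30 gene lists tested, for shMed1 #2 (red) and shMed1 #4 (blue); filled points passed camera at an adjusted p under 0.05. Interferon-stimulated genes had the lowest medians, -1.96 and -1.63.

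Markers of other cell types and signs of RNA quality were read beside these groups. Of 12 leukocyte markers 3 had enough counts to test, Cd14, Csf1r and Cd68, and 1 of them, Cd14, was lower on the mean of both hairpins (2 adjusted over the list alone). Of 9 fibroblast markers 2 were tested and both fell, Pdgfrb (-1.36 and -0.70) and Pdgfra (-0.71 and -0.55), also adjusted over the list alone. Of 7 adipocyte markers 1 was tested, Plin4, which did not pass with either hairpin (adjusted p = 0.342 and 0.0674), and of 9 endothelial markers 0 were tested. Mitochondrial genes took 3.73 to 3.99% of counts in NTC, 3.89 to 3.97% with shMed1 #2 and 4.31 to 4.52% with shMed1 #4. Of 12 mitochondrially encoded genes, 8 were higher and 1 lower on the mean of both hairpins, also adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.211 with an estimated correlation), and the list's adjusted p was 0.42 after a correction for GC content and length. With shMed1 #2 alone that list did not pass (adjusted p = 0.613).

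The last comparison set shMed1 #4 against shMed1 #2. The imprinted gene Peg3 averaged 9.77 CPM with shMed1 #4 and 1.00 CPM with shMed1 #2, a log2 difference of 3.27 (SE 0.268, adjusted p = 1.85e-16), and stood at 3.92 CPM in NTC. Peg3 had 3, 17 and 6 counts in the shMed1 #2 libraries, and without shMed1 #2 replicate 2 the difference was 4.20. Cldn9, Mid1, Morc1, Brinp3 and Cpt1c followed, with differences from 2.43 to 2.96; Cldn9 had 2 to 5 counts and Mid1 2 to 6 counts per library with shMed1 #2, so their differences are imprecise. The lowest with shMed1 #4 were H2-Q6, H2-Q7, Dennd2a, Prl2c3, H2-Q5 and P2ry12, with H2-Q6 at 3.10 CPM against 13.9 CPM (difference -2.16, SE 0.173). Counts of the H2-Q genes and of Prl2c3 are uncertain, since each has near-identical copies. Without shMed1 #4 replicate 2 the difference of H2-Q7 moved from -2.003 to -2.81. The test called 3540 genes, 1758 higher and 1782 lower with shMed1 #4, of which 203 and 65 differed at least 2-fold.

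Antigen presentation genes differed between the hairpins. All 11 tested were lower than NTC with shMed1 #4 (median -0.88, camera adjusted p = 1.46e-09), while 2 were higher and 4 lower with shMed1 #2 (camera adjusted p = 0.178), with the same counts adjusted over the list alone. H2-T23 fell (-1.70 and -1.26) and Tap2 fell (-0.64 and -1.01) with shMed1 #2 and shMed1 #4. On the mean of both hairpins 10 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000109, and adjusted p = 0.0819 with an estimated correlation). Between the hairpins 7 were lower with shMed1 #4 and 0 higher, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.141 with an estimated correlation). Cholesterol biosynthesis genes were higher with shMed1 #4 than with shMed1 #2 in 19 of 23 cases, or 21 adjusted over the list alone (median 0.31, camera adjusted p = 1.47e-10, and adjusted p = 0.042 with an estimated correlation). Endoplasmic reticulum chaperones were higher in 13 of 19 cases and lower in 1, or 15 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 5.87e-08, and adjusted p = 0.141 with an estimated correlation).

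Genes called against NTC with both hairpins in opposite directions numbered 118, and all 118 were also called between the hairpins. That further call was close to assured, since opposite changes from the same controls add up in the difference between the hairpins. Of the 118 genes, 65 were higher with shMed1 #2 and lower with shMed1 #4, led by P2ry12, Cdh2 and Cdh17. The other 53 went the other way, led by Peg3, Brinp3 and Cacng2. Cacng2 fell by 0.99 with shMed1 #2 and rose by 1.17 with shMed1 #4. Some calls of P2ry12, Cdh2 and Cdh17 against NTC were lost with 1 library left out, while the folds kept their direction. The call of P2ry12 with shMed1 #2 was lost without NTC replicate 1 (adjusted p = 0.0508), and with shMed1 #4 without NTC replicate 2 (0.0643), NTC replicate 3 (0.121) or shMed1 #4 replicate 2 (0.131), and in DESeq2 (0.0629). The call of Cdh2 with shMed1 #2 was lost without NTC replicate 3 (0.195) or shMed1 #2 replicate 1 (0.136) and in DESeq2 (0.0961), and with shMed1 #4 without NTC replicate 1 (0.0581), NTC replicate 2 (0.0583) or shMed1 #4 replicate 2 (0.0796). That of Cdh17 with shMed1 #4 was lost without shMed1 #4 replicate 1 (0.0543), where its log2 fold change was -0.56 against -0.68 with all libraries.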

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

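All tests of explanations in this part were chosen after the result had been seen. That of leukocytes was the last of 3 criteria tried on the same markers: one on 8 markers argued against leukocytes, and one on all 12 left them open. The hairpins differed from each other, by the test of the difference itself, in 3540 genes, and 118 of these were called against NTC in opposite directions. Peg3 was higher with shMed1 #4 than with shMed1 #2 by 3.27 on the log2 scale, Cldn9 by 2.96, Mid1 by 2.89, Morc1 by 2.54, Brinp3 by 2.45, Cpt1c by 2.43 and Cacng2 by 2.16. For genes lower with shMed1 #4 the log2 difference was -2.16 for H2-Q6, -2.003 for H2-Q7, -1.89 for Dennd2a, -1.85 for Prl2c3, -1.79 for H2-Q5, -1.78 for P2ry12, -1.60 for Cdh2 and -1.41 for Cdh17. The log2 difference of Peg3 moved to 4.20 without shMed1 #2 replicate 2, and that of H2-Q7 to -2.81 without shMed1 #4 replicate 2, each over 1.5 times as an unlogged fold. Among gene lists, the median difference was 0.31 for cholesterol biosynthesis, 0.28 for endoplasmic reticulum chaperones, 0.25 for mitochondrially encoded genes, 0.19 for fatty acid synthesis, 0.30 for other nuclear receptor targets and 0.42 for Wnt and Notch targets. It was -0.72 for antigen presentation, -0.12 for MYC and ribosome biogenesis, -0.11 for integrins and focal adhesion and -0.10 for glycolysis and hypoxia. With an estimated correlation, the adjusted p of cholesterol biosynthesis was 0.042, and no other of these lists passed.

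Of the 10 splits of the 6 samples in each comparison of 3 against 3, 1 gave as many genes, the real one, and the highest of the other splits gave 0. The real splits of those samples alone called 6087, 3808 and 3367 genes, for shMed1 #2 against NTC, shMed1 #4 against NTC and shMed1 #4 against shMed1 #2. With 10 splits a share under 0.05 cannot be reached. For both hairpins pooled against NTC, 1 of 84 splits gave as many genes, the real one with 3345. The highest other split, with 3034 genes, set shMed1 #2 against the rest, and so follows a group of the design. The split that set shMed1 #4 against the rest gave 138. These counts show that the libraries of a group resemble each other. They cannot exclude chance, since the libraries of a group may be technical repeats.

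Changes were larger with shMed1 #2 than with shMed1 #4: over the 2799 genes called in the same direction the median absolute log2 fold change was 0.416 and 0.323, and 72.8% of these genes had the larger estimate with shMed1 #2. By the test between the hairpins, 845 changed more with shMed1 #2, 99 changed more with shMed1 #4 and 1855 were not called. Offsets for GC content and length left the ratio of the medians at 0.794, against 0.776 without them, which argues against such a trend as the whole cause. Deeper loss of Med1 cannot be told apart from other causes, since Med1 differed by 0.10 on the log2 scale with a 95% interval from -0.08 to 0.28, and protein was not measured. Effects of a hairpin on other transcripts may contribute and were not tested, since the hairpin sequences are not used here.

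Decreases of at least 2-fold outnumbered increases, 316 against 46 on the mean of both hairpins. Among the 8530 genes with a mean of at least 4 log2 CPM the counts were 37 and 10, or 78.7% decreases, which argues against low counts as the whole cause. Most of the 316 decreases were thus in genes below that mean. When only genes above it were tested, calls of any size were more often higher than lower. Decreases made up 88.0% after offsets for GC content and length and at least 87.3% under each of 4 scalings, the main one included. Over these scalings the median log2 fold change of all genes ran only from -0.0406 to -0.0027. They could hardly alter calls of 2-fold, so they do not decide whether normalization plays a part. Also open are the design's own explanation, a dependence of these genes on Med1, and any difference between the control cells and the Med1 hairpin cells that is not Med1.

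Interferon-stimulated genes were lower with both hairpins. A single aberrant library is argued against, since at least 19 list members were called lower with both hairpins whichever of the 9 libraries was left out. Leukocytes among the NTC cells are argued against, if Ptprc and Laptm5, which leukocytes in general carry, are as abundant in them as interferon-stimulated genes: these genes lost a median of 4.70 CPM, whereas Ptprc and Laptm5 had upper 95% bounds of 0.353 and 0.526 CPM in NTC, and 2 of the 12 leukocyte markers, Cd14 and Csf1r, reached that level. With library totals as scale, all 12 summed to 82.4 CPM in NTC, 57.8 CPM with shMed1 #2 and 70.7 CPM with shMed1 #4, mostly Cd14, whereas 8 of them, without Cd14, Csf1r, Cd68 and Lyz2, summed to 0.402, 0.490 and 0.469 CPM. A response of the NTC cells to their own hairpin or culture could also give this pattern and stays open, since there is 1 control hairpin.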

How the results depend on the processing

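The minimum of 4 log2 CPM and the offsets for GC content and length were chosen after seeing the data. No called gene or list among those recomputed reversed its direction under any alternative, but the balance of higher and lower calls turned under some. With a 2-fold minimum the counts of all, higher and lower genes were 613, 102 and 511 for shMed1 #2, 284, 52 and 232 for shMed1 #4, 362, 46 and 316 for the mean of both hairpins, 268, 203 and 65 between the hairpins, and 188, 13 and 175 for both hairpins in the same direction, fewer by construction. With both hairpins pooled as 1 group the mean of both gave 3345 genes, 1717 higher and 1628 lower, since differences between the hairpins then count as spread. With a minimum of 4 log2 CPM, which tests fewer genes, the near even balance became an excess of increases against NTC: 2649 higher and 1937 lower with shMed1 #2, 1739 and 1382 with shMed1 #4, 2413 and 1801 on the mean of both, and 1365 and 963 with both hairpins. Between the hairpins it gave 1275 higher and 1626 lower. Leaving out 1 library kept every count within 1.5 times: 5290 to 6138 for shMed1 #2, 3172 to 3878 for shMed1 #4, 4561 to 5594 for the mean of both, 2817 to 3566 between the hairpins and 2298 to 2803 for both hairpins. Among single named genes 80 results lost their call with a library left out and 6 gained one, and 17 lost it in DESeq2. No pairing by replicate number was visible: correlations of same-numbered samples ran from -0.0555 to 0.0418, and 3 of 9 libraries correlated best with their own number. The labels do not say whether samples of equal number were prepared together. With the replicate number as a block 5892, 3786, 5383 and 3461 genes were called for shMed1 #2, shMed1 #4, the mean of both and between the hairpins, and 2752 with both. The block ended the call of 3 list results: TGF-beta and BMP targets with shMed1 #2 (adjusted p = 0.0575), and MYC and ribosome biogenesis (0.051) and immediate early genes (0.0517) with shMed1 #4. An estimated correlation ended 39 list calls, more than it left standing, and fry, which does not compare a list with other genes, added 26. On the mean of both hairpins 5 sets kept their call with an estimated correlation. They were cholesterol biosynthesis, fatty acid synthesis, other nuclear receptor targets, NF-kB and cytokine genes, and endoplasmic reticulum chaperones. Library size alone moved the share of higher genes among those called from 49.8% to 39.9% with shMed1 #2, 49.8% to 42.2% with shMed1 #4, 49.3% to 39.4% on the mean of both and 49.7% to 58.2% between the hairpins, gave 1123 higher and 1634 lower with both hairpins and 2029 and 1459 between the hairpins, and ended 5 list calls. DESeq2 kept 82.4%, 73.2%, 79.2% and 71.2% of the calls in the 4 contrasts, and the GC content and length offsets 86.7%, 96.0%, 89.5% and 82.7%. These offsets added 4 list calls: immediate early genes on the mean of both hairpins (adjusted p = 0.0253) and with shMed1 #2 (0.0375), YAP/TEAD targets with shMed1 #4 (0.0325), and mitosis between the hairpins (0.0249). They ended 4: Mediator subunits with shMed1 #4 (0.0587) and on the mean (0.0776), and mitochondrially encoded genes (0.42) and histones (0.0528) on the mean. In the simulations 34% to 54% of 1.2-fold changes were recovered, so small changes can be missed at this depth and spread.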

Other observations

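The gene lists in this part and the test on the X chromosome were chosen after the data had been seen. All 8 tested interferon-inducible GTPases, which act against intracellular pathogens, were lower with each hairpin, with medians of -2.17 with shMed1 #2 and -1.72 with shMed1 #4 (mean of both hairpins, camera adjusted p = 8.38e-07, and adjusted p = 0.0438 with an estimated correlation); 2 of them, Gbp2 and Gbp3, are also in the interferon-stimulated list. Irgm1 fell (-1.22 and -1.16), and Gbp2 fell (-1.92 and -1.74). Of 7 complement genes, 5 were lower and 1 higher on the mean of both hairpins (camera adjusted p = 0.00273, and adjusted p = 0.0944 with an estimated correlation). C3, the central complement component, fell from 192 CPM to 90.3 and 83.8 CPM, and C1s1 fell from 164 CPM to 58.2 and 70.8 CPM.

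Of 20 chaperones outside the endoplasmic reticulum, among them the mitochondrial Hspd1 and Hspe1, 15 were higher and 0 lower on the mean of both hairpins (camera adjusted p = 4.03e-06, and adjusted p = 0.0944 with an estimated correlation). Hsp90aa1 rose by 0.48 and 0.25, and Dnajb1 by 0.56 and 0.36. Of 36 proteasome genes, not all of which encode subunits, 14 were higher and 2 lower (camera adjusted p = 0.00273, and adjusted p = 0.174 with an estimated correlation). None of the lists in this part was set against genes of like abundance. Protocadherins and cadherins (22 tested, 2 higher and 6 lower) had a camera adjusted p = 0.032, and adjusted p = 0.174 with an estimated correlation. Most of them, and all interferon-inducible GTPases (0.557 for Irgm2 to 3.40 for Irgm1), averaged below 4 log2 CPM. Most 2-fold decreases lay there too, so these lists may in part be lower through abundance, which was not tested. Imprinted genes (6 tested, 0 higher and 2 lower) and lysosomal genes (24 tested, 7 higher and 6 lower) did not pass, with camera adjusted p = 0.0889 and 0.692.

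Xist fell with both hairpins, and a hypothesis was that a silenced X chromosome may have been reactivated in most cells. The median log2 fold change of 344 X-linked genes, Xist and Tsix left out, exceeded that of 12057 autosomal genes by 0.0015, with an upper 95% bootstrap bound of 0.0404. The bootstrap resampled the X-linked genes, so the bound covers the spread between genes and not between samples. Within that limit, the small difference argues against reactivation across the chromosome in most cells. Loss of a silenced X chromosome would leave this median in place and was not tested.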
